A study of Mus musculus with 6 samples.

How the data were processed

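Hepatocytes of 3 Bim knock-out and 3 wild-type samples were sequenced as single-end libraries of polyadenylated RNA, per the labels. Each sample was put in its group by its title and took its replicate number from there. The deposited data are 6 annotation files, 1 per library, in which each of 118,492 transcripts (48,353 genes, 42,295 loci) carries an estimated read count and an RPKM value, per the file contents. Reads were aligned with TopHat2 (version 2) to GRCm38 (mm10), per the submitters' processing notes. The tool that assigned reads to transcripts is not given in the sources used here, nor is whether it used strand. In the deposited files the estimated read counts of a locus summed to a whole number (within 0.001) for 99.46% to 99.66% of loci, and 92.28% to 92.98% of these totals were even. The deposited RPKM values equal the read count scaled to the transcript length and to a library total of 19,245,556 to 21,899,881 reads, less than the 25,335,211 to 31,130,519 estimated reads the files hold. Because both values are written as text attributes of transcripts and are estimates, the main test was not one made for read counts. Of the methods made for read counts only voom was run, as an alternative described below.

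How the reads were divided affects the values. At loci with a median above 100 reads, over the libraries above 0 with at least 3 of them, 2 of 12,822 library values (0.02%) were exactly 0 at loci with 1 transcript, and 5906 of 32,778 (18.02%) at loci with 2 or more. The share per library was 14.63% to 22.77% at the latter. An exact 0 at such a locus may thus be an estimate that was not made, and genes with zeros are given as the value of each library, with no mean, SD or fold. The fitted difference of such a gene is given for Bcl2l11 alone, and its size depends on the pseudocount.

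Transcript RPKM and reads were summed per gene. Since RPKM is scaled to transcript length, the sum of a gene with several transcripts also depends on which of them the reads were assigned to. Gene names came from a table of Ensembl gene identifiers, which matched 47,993 genes, and 360 were not matched. Coordinates are those of the files. Genes with a mean of at least 1 RPKM over the 6 libraries were tested on log2(RPKM + 1) with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes with a mean-variance trend, two-sided), knock-out against wild-type, all 6 libraries sharing 1 estimate of the spread and no covariate. A difference on this scale understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Single values of 3 against 3 libraries were compared with an exact two-sided permutation test, which cannot give a p below 0.1. Gene lists (37, of which 28 for hepatocyte biology and 9 for other cell types) with at least 5 tested members (30) were tested with camera of limma at a preset inter-gene correlation of 0.01. They were tested again with the correlation estimated from the data and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. None of the lists called with the preset value passed with the estimated correlation after adjustment or with fry (0 each). Levels of a list are means over its members above 0 in all 6 libraries, whether or not they passed the filter. Tests over genes above 0 use those that also passed it (5538 of 6920). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

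The groups, the main test, its filter and pseudocount, the gene lists, the named-gene rule and the alternatives on pseudocount (0.1), filter (none, or a mean of at least 5), scaling, variance model, replicate block, left-out libraries, transcript choice, threshold (0.1) and list test were set before the data were examined. The plan also named tests on whole read counts in case the files held them. They were not run. The alternatives on exact zeros (tested genes above 0 in all 6 libraries, zeros at loci with 2 or more transcripts taken as missing, loci with 1 transcript, and voom weights on the estimated reads divided by 2, since most totals were even) were chosen after seeing the data. So were leaving out the 2 libraries high in interferon genes and estimating the correlation under the settings other than the main one. The 19 lists described one by one were chosen after the list results had been seen.

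Genes were named by a rule: Bcl2l11; the 12 genes read in knock-out and the 12 read in wild-type with the largest differences among those past the test whose groups do not overlap, leaving out models without a proper symbol and pseudogenes (2 genes); in each list described, up to 2 members higher and 2 lower past the test, or else the 2 with the smallest p; and 12 genes of lipid, glucose and redox metabolism always. Names outside the rule are said to be so chosen where they appear, and the members of the lists on cell types, interferon and sex in the closing section were named after their values were seen.

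The scripts for the tests were run on simulated data with known changes in 200 of 5538 genes. Of 100 genes changed by 1 on the log2 scale, limma recovered 55% with no zeros and 32% with zeros put in at a rate of 18%, and of 100 changed by 2 it recovered 86% and 54%. There were 3 false calls with no zeros and 14 with zeros. The simulated genes were those above 0 in all 6 libraries, and zeros were put in gene by gene, only at loci with 2 or more transcripts. In the main test 5483 of 11,021 genes had a library at 0, so these shares need not hold for it.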

Results

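Polyadenylated RNA was sequenced from hepatocytes, the main cell type of the liver, of mice whose Bim gene (symbol Bcl2l11) was deleted through Alb-Cre and of wild-type mice. Alb-Cre expresses the Cre recombinase from the albumin promoter, which is active in hepatocytes. There were 3 knock-out and 3 wild-type libraries, all of the C57BL/6 strain, prepared by collagenase perfusion of the liver. The series addresses the part that BIM, a pro-apoptotic member of the BCL-2 family, plays downstream of the kinase JNK in oxidative stress, fat accumulation and insulin resistance of the liver in obesity. The protocol speaks of male mice, which is taken up with the reads of Xist and Y-linked genes in the closing section. It names a regular chow and a high-fat diet, and the diet of each sample is not given in the labels. Nothing in the labels says that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical. The estimated reads came to 28,245,264, 27,665,120 and 25,335,211 in knock-out replicates 1 to 3 and to 28,258,773, 31,130,519 and 28,131,355 in wild-type replicates 1 to 3. Between 10,486 and 11,255 genes per library had a value above 0. Alb, the gene of serum albumin, named here outside the rule for naming genes, took 2.23% to 5.09% of the reads of a library.

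Bcl2l11 was listed at 0 in all 3 knock-out libraries, with 0 estimated reads in each. In the wild-type libraries it had 0, 680 and 478 estimated reads in replicates 1, 2 and 3 (0, 8.78 and 6.58 RPKM, the read number scaled to transcript length and library size). The gene (ENSMUSG00000027381) lies on chromosome 2 from 128126038 to 128162547 on the plus strand of GRCm38, with 8 annotated transcripts at the locus. All of its reads were assigned to ENSMUST00000103210, a transcript of 5 exons from 128126050 to 128161228. The labels do not say which exons were deleted, so these values are for the transcript as a whole. On the log2(RPKM + 1) scale knock-out minus wild-type was -2.07 (SE 0.97), with a limma adjusted p of 0.941. The size depends on the pseudocount, since with 0.1 in place of 1 the difference of Bcl2l11 was -4.18. The exact two-sided permutation test of 3 against 3 libraries gave p = 0.4, where the smallest p it can give is 0.1. Wild-type replicate 1, at 0 like the knock-out libraries, set that outcome: without it the difference of Bcl2l11 was -3.11 with a limma adjusted p of 0.00549. In that setting 205 of the 207 genes called had a library listed at 0, so passing does not by itself show a loss of Bcl2l11. At loci with 5 to 8 transcripts 18.02% of library values were exact zeros, so a value of 0 alone does not show that the transcript was missing.

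Over all genes, 87 of the 11,021 tested passed the limma test between knock-out and wild-type hepatocytes, 41 with reads in knock-out and 46 with reads in wild-type. Each of the 87 was listed at 0 in all 3 libraries of one group and above 0 in all 3 of the other. In a test chosen after this was seen, the 6 values of each locus were shuffled over the libraries. A median of 86 genes then passed (range 64 to 105 in 100 shuffles). The 87 calls and their adjusted p thus do not show an effect of genotype. Subunits of the respiratory chain stood on both sides. Atp5d, of the mitochondrial ATP synthase, had 4598, 5033 and 4110 estimated reads in the knock-out libraries and was listed at 0 in wild-type (adjusted p = 0.000148). Uqcrq, of complex III, had 3790, 3944 and 3566 reads in knock-out and was at 0 in wild-type, and Ndufc2, of complex I, had 2122, 1988 and 2088. Ndufa9, another complex I subunit, was at 0 in knock-out and had 2462, 2718 and 2676 reads in wild-type. The proteasome subunit Psmb2 had 3312, 3090 and 2822 reads in knock-out and was at 0 in wild-type, and the proteasome subunit Psma5 was at 0 in knock-out and had 4758, 4345 and 4136 in wild-type. Ssr2, of the translocon-associated complex of the endoplasmic reticulum, had 4357, 4285 and 4324 reads in knock-out, and Srp14, of the signal recognition particle, 1708, 1511 and 1684 in wild-type.

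Among the other named genes read in knock-out and listed at 0 in wild-type, Csf1, the macrophage growth factor, had 15,060, 11,036 and 6510 reads. Lpcat3, an enzyme that remodels phospholipids, had 4178, 3356 and 3772 reads, and Hibadh, of valine breakdown, 3007, 3754 and 3296. Cd1d1, which presents lipid antigens, had 1486, 2142 and 1752 reads, and Tmem150a and Ssna1 belonged to this side too. On the other side, Ifnar1, a chain of the type I interferon receptor, had 6452, 5996 and 6040 reads in wild-type and was at 0 in knock-out. Tsg101, of the endosomal sorting machinery, had 2862, 2940 and 2739 reads, and Eif2b2, of the translation initiation factor that the integrated stress response acts on, 2506, 2328 and 2340. Ap1s1, Anapc2, Asna1, Ppme1 and Pi4k2b were likewise read in wild-type and listed at 0 in knock-out. The adjusted p of the 24 named genes lay between 0.000148 (Atp5d) and 0.0265 (Anapc2).

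A single locus on chromosome 14 held a gene on each side. Tm9sf1 (55635965 to 55643806) was read in knock-out with 7141, 8298 and 6972 reads and listed at 0 in wild-type, while its overlapping neighbour Ipo4 (55625400 to 55637895) was at 0 in knock-out and had 7881, 7532 and 7722 reads in wild-type. Both lie on the minus strand, so which of Tm9sf1 and Ipo4 the reads came from is uncertain. For 83 of the 87 genes the whole locus was at 0 in the group listed at 0. All 87 lie in loci with 2 or more annotated transcripts, and at such loci with a median above 100 reads 18.02% of library values were exact zeros, against 0.02% at loci with 1 transcript. Genes that every cell uses had zeros too: at loci with 2 or more transcripts, whatever their read number, 218 of 864 library values (25.2%) of ribosomal protein, oxidative phosphorylation and tricarboxylic acid cycle genes were listed at 0. With the 5538 tested genes that were above 0 in all 6 libraries, limma called 0 genes, and 130 had an unadjusted p below 0.05. The smallest adjusted p in that fit was 0.662, reached by Sept11, a cytoskeletal septin, at 54.8 ± 8.59 RPKM in knock-out and 128.6 ± 6.9 in wild-type (SD, n = 3 each).

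**Figure D1:**
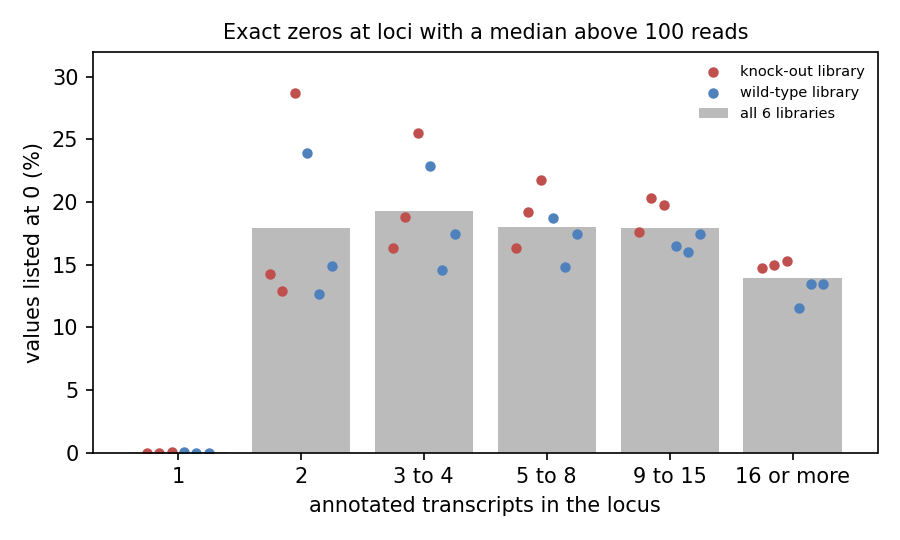
Share of library values listed at exactly 0 (vertical axis, percent) at loci with a median above 100 reads, by the number of annotated transcripts in the locus (horizontal axis). Bars stand for all 6 libraries and points for single libraries; the share was 0.02% at loci with 1 transcript and between 13.91% and 19.25% in the other classes.

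In the fit of these 5538 genes, 329 (5.9%) had groups that did not overlap, where chance gives 10% for 3 against 3. The 130 genes at an unadjusted p below 0.05 in limma are no excess either: other splits of the libraries gave 122 to 525. Beside Sept11, Tmem183a measured 110.5 ± 7.52 RPKM in knock-out and 59.6 ± 3.15 in wild-type (SD, n = 3 each). Ezh2, a histone methyltransferase, measured 15.4 ± 2.71 and 33.6 ± 3.17 RPKM, and Ccdc88a, an actin-binding protein, 4.52 ± 1.39 and 13.2 ± 1.49 (SD, n = 3 each). These 4 genes share the adjusted p of 0.662 and were chosen after their values were seen. The 95% interval of the difference lay within a 2-fold change of RPKM + 1 either way for 4354 genes (78.6%). For low genes this does not exclude a 2-fold change in RPKM.

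Genes of xenobiotic metabolism, the cytochrome P450 enzymes, transferases and transporters that clear foreign compounds, ranked higher in knock-out hepatocytes as a list. Over 42 tested members camera gave an adjusted p of 0.0206. Over the 25 tested members above 0 in all 6 libraries, 21 had a positive difference and the adjusted p was 2.30e-05. With an estimated correlation neither was called (adjusted p = 0.991 and 0.76). None of the members passed the test over all genes (0) or adjusted over the list alone (0), and 4 of the 25 had an unadjusted p below 0.05. The mean level of the list, over the 26 members above 0 whether tested or not, was 3.89 ± 0.24 in knock-out and 3.46 ± 0.27 in wild-type (log2 scale, SD, n = 3 each; exact permutation p = 0.2). Cyp2b9 measured 9.27 ± 0.32 RPKM in knock-out and 5.2 ± 1.49 in wild-type, and Cyp2c37 42.1 ± 8.19 and 24.8 ± 10.6 (SD, n = 3 each). The call over 42 members was lost without knock-out replicate 2 or 3 (adjusted p = 0.371 and 0.114) and without wild-type replicate 1 or 3 (0.806 and 0.0756), and with quantile normalization (0.0621). Wild-type replicate 1 had the highest macrophage and the lowest hepatocyte markers, as given below. Over the 25 members it held without any single library, with adjusted p up to 0.0129.

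Genes of perivenous hepatocytes, those near the central vein of the liver lobule, which share 5 genes with the xenobiotic list, also ranked higher in knock-out. The adjusted p was 0.0129 over 14 tested members and 0.00575 over the 8 above 0 in all libraries, of which 7 had a positive difference. Neither was called with an estimated correlation (adjusted p = 0.991 and 0.76). No member passed the test over all genes (0) or adjusted over the list alone (0), and 1 of the 8 had an unadjusted p below 0.05. The list lay at 5.27 ± 0.16 in knock-out and 4.85 ± 0.19 in wild-type, with no overlap between the groups (log2 scale, SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Cyp2e1, a perivenous cytochrome that makes reactive oxygen, measured 287.8 ± 97.1 RPKM in knock-out and 252.7 ± 131.3 in wild-type (SD, n = 3 each). Znrf3, a brake on Wnt signalling, had 390, 420 and 0 reads in knock-out and was at 0 in all wild-type libraries. The call over 14 members was lost without knock-out replicate 2 (adjusted p = 0.119) and without wild-type replicate 1 (0.144), and with quantile normalization (0.0621). With no filter on low values, which adds members, the list was not called (0.0619). Over the 8 members the call held without any single library (adjusted p up to 0.0358). In wild-type replicate 1 the hepatocyte markers stood at 7.78 on the log2 scale, against 8.25 to 8.74 in the other 5 libraries.

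Genes of fatty acid oxidation and ketogenesis were higher in knock-out as a list only where exact zeros were left out. All 11 members above 0 in every library had a positive difference (adjusted p = 0.00203), and over all 33 tested members the adjusted p was 0.324. With an estimated correlation the adjusted p was 0.872 over the 11 and 0.991 over the 33, so the call was lost. The call rested on wild-type replicate 1, without which the adjusted p was 0.332. In that library macrophage markers stood at 6.59 on the log2 scale, against 2.6 to 3.45 in the other 5, and hepatocyte markers were the lowest (7.78), so markers of cell types moved with this list. The list lay at 4.0 ± 0.14 in knock-out and 3.64 ± 0.35 in wild-type (log2 scale, SD, n = 3 each; exact permutation p = 0.2). Cpt1a, which brings long-chain fatty acids into mitochondria, measured 11.4 ± 1.3 RPKM in knock-out and 9.79 ± 3.1 in wild-type (SD, n = 3 each). Acads, of short-chain fatty acid oxidation, was the 1 member past the test over all genes and adjusted over the list alone (1), at 0 in knock-out and with 2718, 3682 and 3624 reads in wild-type.

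Lipid synthesis and storage genes did not pass the list test. Triglyceride and fatty acid synthesis had an adjusted p of 0.601 over 18 members and 0.2 over the 7 above 0, at 5.74 ± 0.21 in knock-out and 5.48 ± 0.05 in wild-type (log2 scale, SD, n = 3 each; exact permutation p = 0.2). Without knock-out replicate 1 the adjusted p over those 7 was 0.0135, and 0.485 with an estimated correlation. Without the 2 libraries high in interferon genes, described below, these were 0.00509 and 0.549. Scd1, the main fatty acid desaturase of the liver, measured 149.9 ± 22.2 RPKM in knock-out and 96.8 ± 78 in wild-type, and Me1, malic enzyme, 164.5 ± 18.8 and 132.9 ± 24 (SD, n = 3 each). Srebf1, the transcription factor that drives lipid synthesis, had 1632, 0 and 0 reads in knock-out and 2176, 2102 and 2074 in wild-type. Fasn, fatty acid synthase, had 0, 0 and 6274 reads in knock-out and 0, 5312 and 6756 in wild-type. The list of fatty acid uptake and lipid storage had an adjusted p of 0.601 over 16 members and 0.709 over the 9 tested above 0. Cidec, a lipid droplet protein, had 156, 112 and 232 reads in knock-out and was at 0 in wild-type (adjusted p = 0.0715 over all genes). It was the 1 member past the test adjusted over the list alone, and it passed over all genes without knock-out replicate 2 or 3. Apoa4, an apolipoprotein, measured 251.3 ± 51.2 RPKM in knock-out and 163.1 ± 38.1 in wild-type (SD, n = 3 each). The fatty acid transporter Cd36 had 1992 reads in wild-type replicate 1 and was at 0 in the other 5 libraries, and Pparg, a fat-cell regulator, was at 0 in all 6. No member of either list passed over all genes (0 and 0), nor of the synthesis list adjusted over the list alone (0).

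Cholesterol synthesis had an adjusted p of 0.965 over 23 members and 0.748 over the 13 above 0, with means of 6.02 ± 0.16 in knock-out and 6.04 ± 0.2 in wild-type (log2 scale, SD, n = 3 each; exact permutation p = 0.8). Without wild-type replicate 1 the 13 ranked lower in knock-out (adjusted p = 0.0403), a call lost with an estimated correlation (0.97). Msmo1, a sterol methyl oxidase, measured 166.4 ± 28.3 RPKM in knock-out and 368.7 ± 187.7 in wild-type (SD, n = 3 each). Its estimated reads lay closer together, at 7610, 7878 and 9948 in knock-out and 9974, 10,718 and 11,362 in wild-type. The RPKM of Msmo1 thus also reflect which of its transcripts the reads were assigned to. Tm7sf2, a sterol reductase, was at 0 in knock-out and had 1922, 0 and 2144 reads in wild-type. No member passed over all genes (0) or adjusted over the list alone (0).

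**Figure D2:**
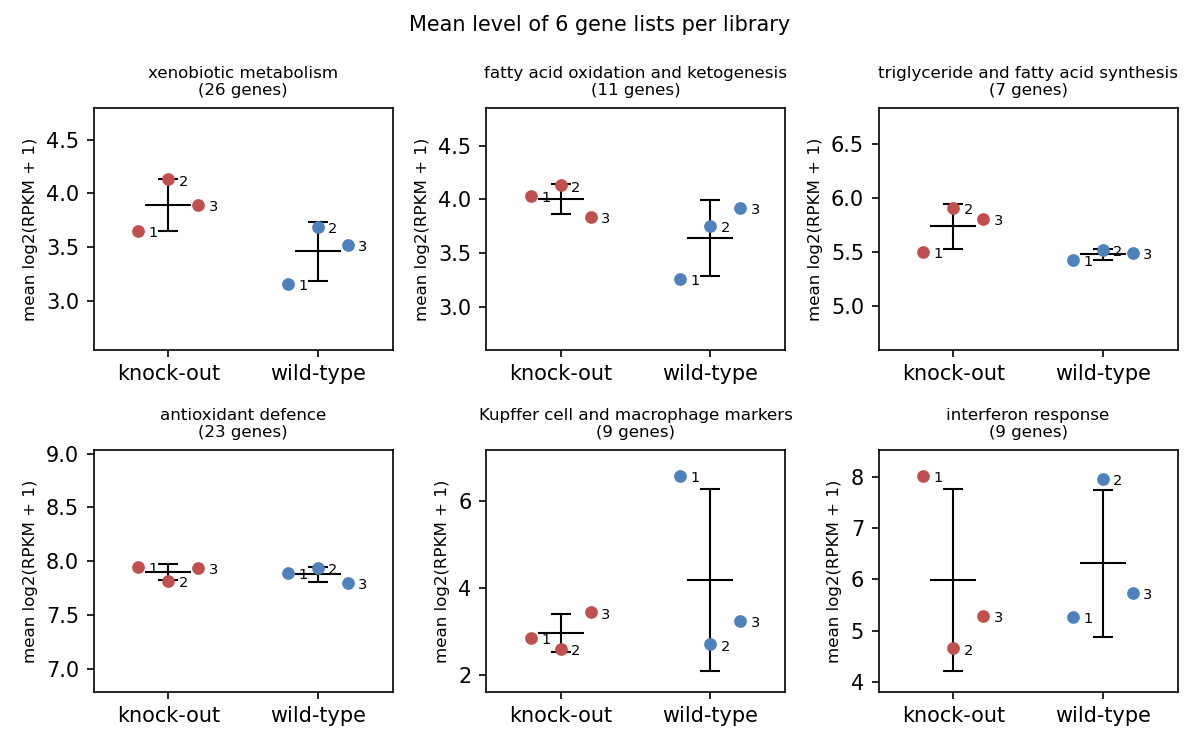
Mean log2(RPKM + 1) of 6 gene lists in each library (vertical axis), over the members above 0 in all 6 libraries, tested or not, for knock-out and wild-type hepatocytes; numbers beside points are replicate numbers, the long line is the mean and the bars are the SD of 3 libraries. Xenobiotic metabolism lay at 3.89 ± 0.24 in knock-out and 3.46 ± 0.27 in wild-type, macrophage markers at 6.59 in wild-type replicate 1, and interferon genes at 8.03 and 7.97 in knock-out replicate 1 and wild-type replicate 2.

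Antioxidant defence, the enzymes and regulators that remove reactive oxygen, differed by less than the spread between libraries. The list lay at 7.9 ± 0.07 in knock-out and 7.88 ± 0.07 in wild-type (log2 scale, SD, n = 3 each; exact permutation p = 0.6), with an adjusted p of 0.78 over 37 members and 0.698 over 23. Nfe2l2, the transcription factor NRF2, had 6592, 5472 and 5550 reads in knock-out and 8572, 0 and 0 in wild-type, and Keap1, its repressor, 0, 2156 and 1826 reads in knock-out and 0 in each wild-type library. NADPH oxidase and other sources of reactive oxygen had an adjusted p of 0.601 over 13 members and 0.698 over 5. The phagocyte oxidase genes stood highest in wild-type replicate 1: Ncf1 had 2872 reads there and was at 0 in the other 5 libraries, and Cybb had 31,464 reads there and 0, 1112, 0, 2128 and 0 in the others. Rac2 had 1124 reads there and 38 to 116 in the other libraries. Nuclear genes of oxidative phosphorylation had an adjusted p of 0.601 over 71 members and 0.338 over the 32 above 0, which ranked higher in knock-out with voom (0.0446, and 0.799 with voom and an estimated correlation). Of the 71, 4 passed over all genes and 4 adjusted over the list alone (Atp5d, Uqcrq and Ndufc2 read in knock-out, Ndufa9 in wild-type), and 0 of the 32 passed in limma, with 3 at an unadjusted p below 0.05. No antioxidant or NADPH oxidase gene passed over all genes or adjusted over its list alone (0 each).

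Glucose and insulin genes gave no call. The list of gluconeogenesis, glycolysis and glycogen had an adjusted p of 0.965 over 12 members. Pck1, a gluconeogenic enzyme, was listed at 0 in all 6 libraries, and G6pc, which releases glucose from the liver, had 4, 4 and 4 reads in knock-out and 2, 8 and 0 in wild-type. Slc37a4, the glucose 6-phosphate transporter, had 364, 296 and 228 reads in knock-out and 172, 0 and 0 in wild-type, and Pcx, pyruvate carboxylase, 0 in knock-out and 1354, 0 and 2432. Insulin signalling had an adjusted p of 0.965 over 28 members and 0.817 over the 9 tested above 0. The 11 members above 0, tested or not, lay at 3.52 ± 0.04 in knock-out and 3.53 ± 0.08 in wild-type (log2 scale, SD, n = 3 each; exact permutation p = 1.0). Irs2, an insulin receptor substrate, measured 1.67 ± 0.29 RPKM in knock-out and 1.62 ± 0.4 in wild-type (SD, n = 3 each). The kinase Akt1 had 4946, 0 and 0 reads in knock-out and 5388, 5618 and 5856 in wild-type, and Akt2 had 0, 3945 and 0 in knock-out and 3681, 3759 and 4207 in wild-type. No member of either list passed over all genes or adjusted over the list alone (0 each).

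The lists on cell death and stress kinases likewise held no member past the test over all genes or adjusted over the list alone (0 each). The BCL-2 family and caspases had an adjusted p of 0.965 over 26 members and 0.709 over the 11 tested above 0. The 12 members above 0, tested or not, lay at 4.22 ± 0.27 in knock-out and 4.54 ± 0.37 in wild-type (log2 scale, SD, n = 3 each; exact permutation p = 0.4). Bid, a pro-apoptotic relative of BIM, measured 84.5 ± 11 RPKM in knock-out and 65.8 ± 7.06 in wild-type (SD, n = 3 each), and Bcl2l12 had 170, 266 and 0 reads in knock-out and 0 in each wild-type library. The JNK pathway had an adjusted p of 0.965 over 22 members and 0.698 over 10. Mapk8, the gene of JNK1, was at 0 in knock-out and had 1426, 0 and 1146 reads in wild-type. Jund, a subunit of the transcription factor AP-1, measured 42.8 ± 7.96 RPKM in knock-out and 30.1 ± 2.07 in wild-type (SD, n = 3 each). The unfolded protein and integrated stress response had an adjusted p of 0.914 over 34 members and 0.254 over 19. Atf5, one of its transcription factors, measured 302.7 ± 27.7 RPKM in knock-out and 268.7 ± 29.4 in wild-type (SD, n = 3 each), and Asns, asparagine synthetase, had 0, 0 and 4264 reads in knock-out and 6492, 5786 and 4578 in wild-type.

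Markers of Kupffer cells and macrophages, the phagocytes of the liver, ranked lower in knock-out (adjusted p = 0.00268 over 24 members and 0.00438 over the 9 above 0), and wild-type replicate 1 carried this difference. Both calls were lost with an estimated correlation (adjusted p = 0.991 and 0.872). Their mean level was 2.86, 2.6 and 3.45 in the knock-out libraries and 6.59, 2.71 and 3.26 in wild-type replicates 1 to 3 (log2 scale). Without wild-type replicate 1 the adjusted p was 0.993 and 0.845. Marco, a scavenger receptor of macrophages chosen after its values were seen, measured 2097 RPKM in that library and 33.3 to 59.1 in the other 5. Mpeg1, a pore-forming protein of macrophages, measured 77.7 RPKM there and 5.73 to 20.8 elsewhere, and Cd68 had 6732 reads there, 966 in wild-type replicate 2 and 0 in the other 4 libraries. No member passed over all genes or adjusted over the list alone (0 each). Of 9 lists for other cell types, the other one with enough tested members was that of sinusoidal endothelial cells, with an adjusted p of 0.553 over 6. Its members Eng and Fcgr2b had 870 and 1206 reads in wild-type replicate 1, against 0 to 130 and 63 to 133 in the other libraries. The remaining 7 lists (stellate cells and fibroblasts, cholangiocytes, lymphocytes, neutrophils, erythroid cells, adipocytes and pancreatic acinar cells) had fewer than 5 tested members each.

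Hepatocyte markers had an adjusted p of 0.101 over 26 members and 0.0617 over the 19 above 0. Without wild-type replicate 1, where these markers were lowest, the adjusted p was 0.955 and 0.861, and the test over the 19 pointed lower in knock-out. The 19 were called higher in knock-out without knock-out replicate 3 (0.0197) or wild-type replicate 2 (2.35e-07), without the 2 interferon-high libraries (1.53e-05), with the replicate number as a block (0.0391) and with voom (0.0137). The 26 were called without wild-type replicate 2 (4.24e-05) and with the block (0.0302). With an estimated correlation the adjusted p was 0.991 and 0.872 with all libraries, and none of those calls held (0.922, 0.459, 0.634, 0.87 and 0.661 over the 19, and 0.806 and 0.985 over the 26, in the order given). Apoa2, an apolipoprotein of high-density lipoprotein, measured 3024 ± 515.9 RPKM in knock-out and 2307 ± 179.2 in wild-type, and Ass1, of the urea cycle, 366.1 ± 22.8 and 316.5 ± 55.3 (SD, n = 3 each). Female-biased liver genes ranked higher in knock-out over the 9 tested members above 0 (adjusted p = 0.0436), while over 14 members the outcome depended on the setting. Those 14 had an adjusted p of 0.132 with all libraries, and were called without knock-out replicate 1 (0.0429) or wild-type replicate 2 (0.0032) and with the replicate block (0.0302). With no filter, which adds members, the list was called too (0.0428). With an estimated correlation the adjusted p was 0.872 over the 9 and 0.991 over the 14. It was 0.989, 0.806 and 0.985 over the 14 in those 3 settings, and 0.976 with no filter. The call over the 9 was lost with median-of-ratios scaling (0.0983) and when any one library other than wild-type replicate 2 was left out, with adjusted p from 0.0692 without knock-out replicate 3 to 0.861 without wild-type replicate 1. Its member Cyp2b9 passed adjusted over the list alone in that fit, 1 of 9, and Sult2a2, a sulfotransferase, had 0, 351 and 398 reads in knock-out and 0 in each wild-type library. The remaining 11 lists tested had adjusted p between 0.601 and 0.989, and between 0.253 and 0.817 over the tested genes above 0 in all libraries. Some were called with a library left out. Without wild-type replicate 2 ribosomal proteins ranked lower in knock-out (0.00575, and 0.035 over genes above 0) and the acute phase higher (0.0372 and 0.000638), as did periportal genes (0.00159) and p53 targets (0.0235) over genes above 0. Immediate early genes ranked higher without wild-type replicate 1 over genes above 0 (0.0305). In that setting ribosomal proteins and the acute phase (0.861 each), periportal genes (0.785) and p53 targets (0.691) were not called. Over those genes the acute phase (0.000552) and periportal genes (0.00727) also ranked higher without the 2 interferon-high libraries, and p53 targets with voom (0.0446). None of these calls held with an estimated correlation in the same setting (0 lists). The median, the mean and the test of a list differed in sign in 13 of the 30 lists tested and in 3 of the 28 tested over genes above 0, and 0 of these lists were called with all libraries in those fits. The remaining 11 covered bile acids, the tricarboxylic acid cycle, immediate early genes, the acute phase, the circadian clock, male-biased and periportal genes, proliferation, p53 targets, ribosomal proteins and neighbours of Bcl2l11 on its chromosome. Arntl, a core clock gene named after its values were seen, was the 1 member of these lists past the test over all genes, at 0 in knock-out and with 626, 972 and 664 reads in wild-type.

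The first 2 principal components followed single libraries and not genotype. Over the 5538 tested genes above 0 in all libraries, the correlation across genes between libraries was 0.964 on average within groups and 0.966 between groups. The first principal component (43.3% of the variance) set wild-type replicate 1, at 41.4, apart from the other 5 libraries, at -14.8 to 0.4. On the second (20.9%) knock-out replicate 1 and wild-type replicate 2 stood at 12.6 and 19.5, above the other 4 libraries. Those libraries were also the highest in interferon response genes, a list with an adjusted p of 0.965 over 38 members and 0.513 over 9. Without both of them the 9 still ranked lower in knock-out (adjusted p = 0.0241). Without knock-out replicate 1 the interferon list ranked lower in knock-out (adjusted p = 0.0429, and 0.000112 over the 9), without wild-type replicate 1 lower over the 9 (0.0403), and without wild-type replicate 2 higher over the 38 (0.0323). All 5 calls were lost with an estimated correlation, with adjusted p of 0.668, 0.989 and 0.93, 0.97, and 0.816. Of its members, Irf7, an interferon regulatory factor, had 9818, 4158 and 4618 reads in knock-out and 2842, 0 and 0 in wild-type, and Ifi27 had 0 in knock-out and 0, 1526 and 2948 in wild-type. Over all 11,021 genes the mean correlation across genes was 0.568 within and 0.572 between groups.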

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

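The settings with exact zeros left out or taken as missing, the one at loci with 1 transcript, those without the 2 libraries high in interferon genes, and those that join an estimated correlation to another setting, were chosen after the results were seen, and the other settings were planned. Against 87 genes (41 higher, 46 lower), between 81 and 99 were called under another pseudocount, filter, scaling or variance model or at an adjusted p of 0.10, with 79 to 87 of the same genes among them. With the top transcript of each gene 80 were called, 41 of them the same. Leaving out 1 library gave 182 to 207 genes (73 to 111 higher, 87 to 127 lower), with 80 to 83 of the 87 among them. Of the genes called so, 177 to 205 had a library at 0. The cause was not tested. With the replicate number as a block (replicate block), limma called 0 genes (0 higher, 0 lower), with 198 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0505, and 5 lists. Deviations from the group means correlated at -0.16, -0.05 and -0.01 between same-numbered libraries, and no library correlated best with its own number. The highest correlation was 0.31, between knock-out replicate 1 and wild-type replicate 2. No sign of pairing by number was thus seen. Since the spread followed single libraries, these values cannot exclude it. Over tested genes above 0 in all 6 libraries limma called 0 genes (0 higher, 0 lower) in every setting run: as such (130 unadjusted), with the replicate block (157), with median-of-ratios scaling (139), with a pseudocount of 0.1 (128), without each library in turn (81 to 252, 0 to 0 called), without the 2 interferon-high libraries (153) and with voom (72). It also called 0 with zeros as missing (197) and at loci with 1 transcript (46). None of the 87 is in any of these fits, which leave out genes with a whole group at 0 or loci with 2 or more transcripts, so their 0 calls say nothing about the 87.

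Against 3 lists called, quantile normalization gave 1, leaving out 1 library 0 to 8 (0 without wild-type replicate 1), and an estimated correlation and fry 0 each, which also took the marker lists of other cell types from 1 to 0. Marker lists called without 1 library were 0 to 1. Over genes above 0 the lists called were 5, and with the replicate block 6, with median-of-ratios scaling 4, with a pseudocount of 0.1 5, at loci with 1 transcript 5, without 1 library 4 to 10, without the 2 interferon-high libraries 10, with voom 8, and 0 with an estimated correlation or fry; the cause was not tested. With an estimated correlation 0 lists (0 marker lists) were also called under every other setting that had a list test, where fry was not run. Bcl2l11 went from -2.07 to -4.18 with a pseudocount of 0.1 and to between -3.11 and -1.46 without 1 library, and passed the test (adjusted p = 0.00549) without wild-type replicate 1, which was listed at 0; it did not pass in any other setting (adjusted p 0.842 to 0.999). Of 64 named genes tested 25 were called; 25 lost the call with the replicate block, 17 with the top transcript and 1 to 2 without 1 library. Named genes newly called were Srebf1, Keap1, Akt1 and Sult2a2 without knock-out replicate 1, Cidec and Akt2 without knock-out replicate 2, and Znrf3, Cidec, Bcl2l12 and Asns without knock-out replicate 3. They were Nfe2l2, Slc37a4, Irf7 and Ifi27 without wild-type replicate 1 and Mapk8, Tm7sf2 and Pcx without wild-type replicate 2, each listed at 0 in at least 1 library. Cidec was also called with a pseudocount of 0.1, with no mean-variance trend and at an adjusted p of 0.10, and Akt2 with the top transcript. None of the called genes reversed direction (0), which was judged only for genes past the test. The mean correlation between libraries (0.57) was 0.472 with a pseudocount of 0.1, 0.692 with no filter, 0.484 with a mean of at least 5, 0.469 with the top transcript, 0.965 over genes above 0, 0.964 at loci with 1 transcript and 0.563 to 0.589 without 1 library (0.962 to 0.975 over genes above 0, with 0.963 without knock-out replicate 1 or 3). The planned tests on whole read counts were not run, since the files hold estimates. Depth limits low genes such as G6pc, with 0 to 8 reads.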

Other observations

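Every test reported here was chosen after the result it bears on was seen, except the one on genes that every cell uses being at 0 in all 6 libraries.

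Interferon response genes, induced by antiviral signalling, were highest in 2 libraries, 1 of each genotype. All 9 that were above 0 in every library were higher in knock-out replicate 1 and wild-type replicate 2 than in the other 4 libraries. Isg15, a ubiquitin-like antiviral protein, measured 504.7 and 508.1 RPKM there and 39.5 to 108.5 in the others, and Ifit3, which is induced with it, 508.4 and 578.5 against 5.3 to 18. Usp18, which removes Isg15 from proteins, measured 1076.8 and 488.2 RPKM against 38.4 to 206.3, and Ifit1 167.1 and 128.6 against 6.2 to 21.7. These are values of single libraries, and the 2 were not tested as a group.

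The 87 genes past the test all had 1 group at 0 and the other read in all 3 libraries, at loci with 2 or more transcripts. A candidate explanation is that the division of reads between transcripts failed at random in single libraries. When the 6 values of each locus were shuffled over the libraries, 47 of 100 shuffles gave at least 87 genes (median 86, range 64 to 105). The shuffle keeps the zeros whatever made them, so it cannot tell failed estimates from absent RNA. Some zeros followed the level: interferon genes were at 0 in 12.5% and 10.0% of members in knock-out replicate 1 and wild-type replicate 2, against 40.0% to 47.5% in the others. The 10 splits of the libraries, 3 against 3, are too few for a share under 0.05: 5, the real one included, gave 87 or more genes, and the highest other gave 105. The same holds for the lists, with 3 called and a highest other of 8 (8 of 10 splits as large), and over genes above 0 with 5 called and a highest other of 11 (5 of 10). An effect of the Bcl2l11 deletion on the tested genes above 0 in all libraries stays open, with a smallest adjusted p of 0.662. For 78.6% of them a change of RPKM + 1 beyond 2-fold lay outside the 95% interval. For low genes among them a 2-fold change in RPKM is not excluded by this.

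Macrophage genes were high in wild-type replicate 1. All 9 markers above 0 in every library exceeded the highest other library there, at a median of 13.6 times the mean of the other 5 (5.7 to 42.8), led by Marco (84,562 reads against 1272 to 2336), Cd5l (9380 against 154 to 294) and C1qa (3724 against 116 to 288). RNA of macrophages carried through the perfusion may be the source, as a hypothesis. The wild-type genotype as the source is argued against by the other wild-type libraries, which both exceeded the 3 knock-out libraries in 0 of the 9 markers. A lower share of hepatocytes alone would raise the markers of every other cell type alike. Those with at least 10 reads in every library, only 4, had a median of 1.23 times (exact rank test against the macrophage markers, p = 0.0336). They cannot decide this, since the bound leaves out markers near 0 elsewhere and the folds come from a single library. Eng, an endothelial marker left out so, had 870 reads there and 0 to 130 in the others. The endothelial list stood at 1.2 there (log2 scale) and at 0.35 to 0.49 in the other 5. Sox9 stood at 1.08, Cela1 at 1.05 and Tagln at 1.39 times, and Fcgr2b, which macrophages also express, at 11.66. The median hepatocyte marker stood at 0.65 times, with 18 of 19 below the mean of the other libraries. Whether there were more macrophages or more RNA of these genes in each stays open.

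The protocol speaks of male mice, yet Xist, the RNA of the inactive X chromosome of female cells, had 25,083 to 38,904 reads in each of the 6 libraries, and the Y-linked genes Kdm5d, Eif2s3y, Uty, Ddx3y, Zfy1 and Zfy2 were listed at 0 in all 6. Their X-linked relatives Kdm5c and Eif2s3x had at least 6164 and 13,306 reads. Zeros from failed estimates in male samples would leave Xist unread, which its lowest value of 25,083 argues against; failed estimates at the Y loci by themselves are argued against by their number. Of genes that every cell uses 4.9% were at 0 in all 6 libraries (7 of 144; exact binomial 95% interval 2.0% to 9.8%), which is not clearly under the 5% set beforehand. At the upper limit of that share all 6 Y genes at 0 have an exact binomial p of 8.6e-07, if they fail independently. The share is that of genes every cell uses, so this p makes no allowance for Y genes that hepatocytes may hardly express. Female animals may be the source, as a hypothesis: at loci with 1 transcript the median reads of female-biased genes exceeded those of male-biased genes in 5 of 6 libraries (131 to 364 against 19 to 35). In wild-type replicate 1 they were 10 against 41. These medians compare different genes with no male sample beside them, so they cannot decide the sex. The Xist reads, highest in wild-type replicate 1 (38,904), argue against male samples in all 6 libraries.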
